A study of Mus musculus with 5 samples.

How the data were processed

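Single-cell RNA was measured with the 10x Genomics Chromium 3' v3 chemistry in 5 libraries of sorted CD45 and CD11b positive cells from newborn mouse spinal cord, 1 from intact cord, 2 from 3 days and 2 from 5 days after crush. Per the file headers, the deposited values are raw UMI counts per gene and barcode made by Cell Ranger 3.0.2. The submitters' processing notes also name CASAVA, without a version, and the genome build GRCm38. The count matrices were not limited to cells and held 6794880 barcodes and 31053 genes each. Of these genes, 31011 had the same Ensembl ID in the annotation used for positions, and 71 shared a symbol with another.

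A barcode was called a cell at or above 10% of the 99th percentile of the UMI totals of the 3000 largest barcodes, with at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs. Scrublet's automatic threshold called 2, 977, 0, 0 and 3 doublets, so the barcodes with the highest scores were removed at 0.8% per 1000 cells instead. Values were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours gave Leiden clusters at resolution 1. Each cluster's marker levels were divided by those of the highest cluster, or by 200 CPM where that was higher, and it took the class with the highest median. It stayed unnamed with fewer than 20 cells, a median under 0.2, or fewer than 3 markers at that level. It also stayed unnamed with a second class at 0.2 or more (or at 0.1 and at least 0.333 of the best), or with more markers of another class than its own among its leading 10 genes. The last reasons were a median UMI count of at least 2 times that of its libraries, or under 0.333 of it with no marker among those genes.

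The first naming level of 0.3 was lowered to 0.2, and the criteria on second classes and multiplets were added, after cluster markers were seen. Free RNA was profiled in droplets with 1 to 100 UMIs. Its share of the microglia-like sums was first the median over lists of other classes (11.8 to 20.8%) and was changed after seeing the data to the highest list under 10% (3.72 to 6.55%). Erythroid genes gave 0.00793 to 0.0325% and fibroblast or pericyte genes 0.110 to 0.346%, so the true share may be far lower than the share used. A gene was marked when over 20% of its counts could come from free RNA over all 5 libraries. Benjamini-Hochberg adjustment over lists was taken jointly over the 36 lists tested.

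Raw UMI counts were summed per library over the microglia-like cells, and over the border-associated macrophage-like cells, and tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). The 3 groups shared 1 estimate of the spread, with 2 residual degrees of freedom, a median prior of 11.9 degrees and a biological coefficient of variation of 4.73% (6.20% in border cells). Fold changes are edgeR's, and CPM are scaled by TMM. RNA of microglia in the border sums was bounded, after seeing the data, from unscaled CPM by the median ratio of the 12 microglia markers to their microglia-like level. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated one, and with fry. DESeq2 1.42.0 and limma-voom were alternatives. Other tools were Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.

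The classes' markers, 23 gene lists, 16 marker lists, tests and alternatives were chosen before the data were examined, except where stated. Of the marker lists, 13 were tested, since only lists of other classes were to be tested in microglia-like sums, and mast cell and ependymal markers had fewer than 3 tested genes. Named genes were, per comparison, the 8 highest and 8 lowest fold changes among genes past the test with a mean of at least 32 CPM and libraries of the groups not overlapping, up to 4 members of each list past the test with the largest fold changes, and 12 genes fixed beforehand. Predicted genes, mitochondrial genes and ribosomal protein genes were not named among the 8. In border-associated macrophage-like cells they were the 8 highest, the 8 lowest and the 12 fixed genes, without list members. Xist and Y-linked genes were read once. Some single genes are not reported here and were left out of the named genes after these were chosen, and all tests and counts of tested genes include them.

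Intervals are exact Clopper-Pearson 95% intervals and cover counting error only, and a share of 0 allows 3 counts. Cells were thinned to 2000 UMIs before shares of cells with a UMI, or with at least 3 UMIs over a cell-cycle list, were counted. On simulated data with 200 changed genes, the edgeR test recovered 59.7% to 70.1% of genes changed 1.5-fold, 76.1% to 88.1% at 2-fold and 89.4% to 93.9% at 4-fold, with 7 to 9 false calls, and made 0 calls with no gene changed. The simulation gave all genes the same mean spread and the 0 dpi library the spread of the others, so it does not test these assumptions. It also changed far fewer genes than were called in the data. Alternatives changed the cell calling, mitochondrial limit, doublets, clustering, class, cycling cells, free RNA, depth, scaling, filter, test, fold threshold and libraries, 1 at a time. Barcode lists were not used here.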

Results

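To study how microglia of the newborn mouse spinal cord change after injury, single-cell RNA profiles were compared between intact cord and cord crushed 3 or 5 days earlier. Cells positive for CD45 and CD11b, surface proteins of leukocytes and of microglia and other myeloid cells, had been sorted from a 1 mm piece of lower thoracic cord around the crush, or from intact cord, of wild-type C57BL/6 mice. The 5 libraries formed 3 groups: 1 library at 0 days post injury (0 dpi, postnatal day 2), 2 at 3 dpi (postnatal day 5) and 2 at 5 dpi (postnatal day 7). Postnatal age therefore rose with time after injury in every comparison. The labels did not say whether libraries came from separate animals, so p-values measured only the spread between these libraries, which may be technical.

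Total counts of unique molecular identifiers (UMIs) were 127985695 at 0 dpi, 163802006 and 182128531 at 3 dpi, and 110716810 and 118750895 at 5 dpi. After filtering, 6393 cells remained at 0 dpi, 4462 and 4399 at 3 dpi, and 3077 and 3199 at 5 dpi. Median UMIs per cell were 10212 at 0 dpi, 22321.5 and 24789 at 3 dpi, and 18481 and 19210 at 5 dpi. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom over genes of 23.3 at 3 dpi and 3.35 at 5 dpi, which does not tell separate animals from separate captures of the same cells.

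Microglia-like cells, named by markers such as P2ry12, Tmem119 and Sall1, made up 93.7% of sorted cells at 0 dpi (exact 95% interval 93.0 to 94.2), 47.3% ± 2.09 at 3 dpi and 59.9% ± 1.37 at 5 dpi (SD, n = 2). Border-associated macrophage-like cells, with Mrc1, Lyve1 and Pf4, were 1.09% at 0 dpi (0.855 to 1.38), 8.39% ± 0.746 at 3 dpi and 4.41% ± 0.617 at 5 dpi. Monocyte-like cells, with Ccr2, Ly6c2 and Plac8, were 0.156%, 5.23% ± 0.483 and 3.43% ± 0.491. Oligodendrocyte lineage-like cells were 0.125%, 0.394% ± 0.108 and 0.941% ± 0.0935, and endothelial-like cells were 0 of 6393 cells at 0 dpi, which allows up to 0.0469%, then 0.237% ± 0.0136 and 0.285% ± 0.127. Both injured groups differed from the intact library by more than the spread between their replicates in the microglia-like, border macrophage-like and monocyte-like shares. Shares were not tested. Between 3 and 5 dpi, 2 against 2 libraries allow an exact two-sided permutation p no smaller than 0.33.

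Clusters that carried markers or leading genes of another class stayed unnamed, by thresholds set after the data were seen, and held 4.91% of cells at 0 dpi, 31.2% ± 1.43 at 3 dpi and 26.6% ± 1.99 at 5 dpi. Clusters in which no class reached the marker level held 0.0313%, 7.10% ± 0.264 and 4.37% ± 0.714. Unnamed clusters were led by Plac8, Retnlg, Camp, Gzma, Igkc, H2-Eb1, Ctsk or Ms4a7, among others. In some of them microglia was the best class, while in others, such as those led by Camp and Igkc, it was not. The largest, led by Plac8 and with microglia as best class, held 0.720% of cells at 0 dpi, 7.49% and 7.64% at 3 dpi, and 5.13% and 4.03% at 5 dpi. Part of the lower microglia-like share after injury therefore depends on the rule that left such clusters unnamed. The shares also depend on the sort gate and on the UMI threshold, which was 6999 at 0 dpi and 9865 to 12351 in the injured libraries. With a mitochondrial limit of 5%, close to the median of 5.43% at 0 dpi and below that of the injured libraries, the microglia-like share was 15.9% at 3 dpi and 26.3% at 5 dpi. That limit left 2184 microglia-like cells at 0 dpi, 189 and 221 at 3 dpi, and 95 and 113 at 5 dpi. Calls lost under it therefore rest on far fewer cells.

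**Figure D1:**
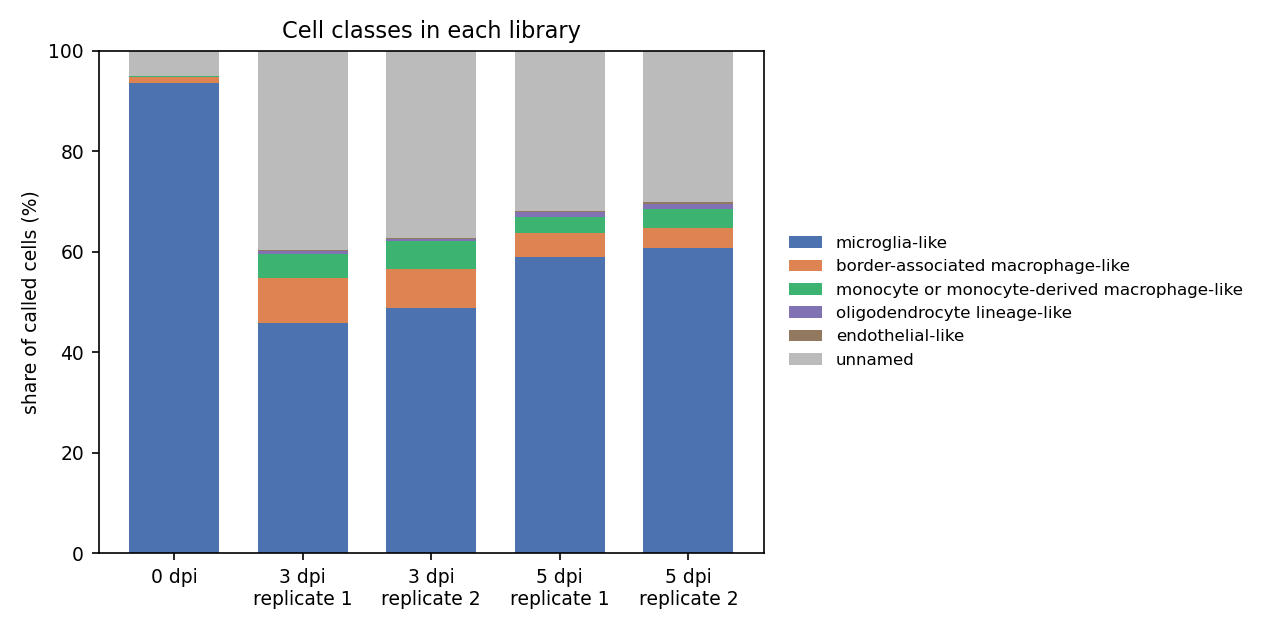
Stacked bars give the percentage of called cells (vertical axis) in each class, with 1 bar per library. The microglia-like share is 93.7% at 0 dpi and has means of 47.3% at 3 dpi and 59.9% at 5 dpi.

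Most microglia-like cells of each group lay in different clusters. At 0 dpi, cluster 0 (led by Crybb1, Klf2 and Fscn1) held 52.7% of them and cluster 4 (Mcm5, Mcm6 and Mcm3) 16.5%. At 3 dpi, cluster 1 (Apoc1, Ctsl and Hebp1) held 65.7% and 68.4%. At 5 dpi, cluster 3 (Lag3, Adgrg1 and Xist) held 39.5% and 43.8%, and cluster 2 (Cd9, Lpl and Cadm1) 34.4% and 30.6%. The comparisons of genes summed all microglia-like cells of a library, which gave 75588419 UMIs at 0 dpi, 47280907 and 55253724 at 3 dpi, and 36349866 and 42300583 at 5 dpi, and tested 14253 genes.

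The first comparison asked what differed in microglia-like cells 3 days after the crush. Fn1, which encodes the matrix glycoprotein fibronectin, rose from 1.69 CPM (counts scaled to library size) at 0 dpi to 548 ± 17.6 at 3 dpi (SD, n = 2), 323-fold (log2 fold change 8.33, SE 0.114, edgeR adjusted p = 4.17e-15). Spp1, encoding the secreted phosphoprotein osteopontin, rose from 46.7 to 3635 ± 409 CPM, 77.9-fold (log2 fold change 6.28, SE 0.117, edgeR adjusted p = 3.16e-12). Wfdc17, a small secreted protein, Pla2g7, a lipoprotein-associated phospholipase, Gpnmb, a membrane glycoprotein of phagocytes, and Cd72, a lectin-type receptor, rose by log2 5.60, 5.58, 5.20 and 4.24. Crybb1, a crystallin expressed by microglia, fell from 868 to 159 ± 6.54 CPM (log2 fold change -2.45, SE 0.0569, edgeR adjusted p = 4.99e-13). The actin-bundling Fscn1 (-2.20), the cyclin Ccnd1 (-1.98), the adaptor Bank1 (-1.92) and the transcription factors Ets1 (-1.77) and Sox4 (-1.69) fell as well.

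In all, 8375 of 14253 genes passed edgeR's quasi-likelihood test at an adjusted p under 0.05, 4088 higher and 4287 lower at 3 dpi, and 2029 of them were at least 2-fold apart. The 0 dpi group was 1 library, whose spread was assumed to be that of the 3 and 5 dpi pairs. With a mitochondrial limit of 5%, 4129 genes passed. At the share used, which may be too high, free RNA could give 100% of Fn1, 58.4% of Wfdc17 and 22.4% of Spp1 counts at 0 dpi. At the median of the lists it could give 100% for Spp1, so these fold changes depend on that background. When the marker level that names a class was raised to 0.3, Gpnmb no longer passed (log2 3.64).

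Genes of resting microglia fell. Of 22 homeostatic genes tested, 1 was higher, 18 were lower and 3 did not pass the test (1 higher and 19 lower adjusted over the list alone). Homeostatic genes had a median log2 fold change of -0.79 (camera adjusted p = 2.82e-06, adjusted p = 0.290 with an estimated correlation). P2ry12, a receptor for ADP, fell from 1894 to 630.3 ± 10.9 CPM (log2 -1.59), and Tmem119, a membrane protein used as a microglial marker, from 663 to 232 ± 1.91 CPM (-1.51). The list holds all of the fixed microglia markers, so cells with low levels of it can fall outside the class. Of 23 axon-tract and disease-associated genes tested, 22 were higher, 1 was lower and 0 did not pass the test (22 higher and 1 lower adjusted over the list alone). Axon-tract and disease-associated genes had a median log2 fold change of 1.27 (camera adjusted p = 1.85e-09, adjusted p = 0.408 with an estimated correlation). Igf1, a growth factor, rose from 18.1 to 130.1 ± 11.5 CPM (2.85), and Apoe, a lipid carrier, from 8468 to 33051 ± 1977 CPM (1.96). That list was in part chosen by the study on these samples and is not independent evidence. Lgals3, a galectin, was higher by log2 3.63 (edgeR adjusted p = 0.0251), a call that was lost without either 5 dpi library. Clec7a was not among the listed features.

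Of 26 genes of matrix proteins and their receptors tested, 18 were higher, 1 was lower and 7 did not pass the test (18 higher and 1 lower adjusted over the list alone). Matrix and matrix receptor genes had a median log2 fold change of 1.63 (camera adjusted p = 4.82e-06, adjusted p = 0.290 with an estimated correlation). Besides Fn1, Thbs1, encoding thrombospondin 1, was higher (1.71), though 31.2% of its counts could come from free RNA. Of 24 endopeptidase inhibitor genes tested, 16 were higher, 3 were lower and 5 did not pass the test (18 higher and 3 lower adjusted over the list alone). Endopeptidase inhibitor genes had a median log2 fold change of 2.24 (camera adjusted p = 0.000166, adjusted p = 0.290 with an estimated correlation). Its members BC100530, Timp1, A2m, Serpinb8 and Slpi had 100%, 100%, 49.1%, 43.5% and 36.5% of their counts within reach of free RNA, and the list kept its call with free RNA subtracted. Of 13 annexin and S100 genes tested, 11 were higher, 1 was lower and 1 did not pass the test (11 higher and 1 lower adjusted over the list alone). Annexin and S100 genes had a median log2 fold change of 1.46 (camera adjusted p = 2.41e-05, adjusted p = 0.337 with an estimated correlation). Anxa5, a phospholipid-binding protein, rose by log2 2.53, and Anxa1 was at 3.72, with 96.5% of its counts within what free RNA could give, and did not pass with free RNA subtracted. These 3 lists follow themes that the study is known to name from the same samples, so they are not independent evidence. Of 20 genes of lipid uptake, storage and efflux tested, 20 were higher, 0 were lower and 0 did not pass the test (20 higher and 0 lower adjusted over the list alone). Lipid uptake, storage and efflux genes had a median log2 fold change of 1.97 (camera adjusted p = 1.95e-09, adjusted p = 0.299 with an estimated correlation). The lipid carriers Apoc1 (4.09) and Fabp5 (3.97) and the scavenger receptor Cd36 (3.44) were among those that rose. Cd36 was low, at 0.907 CPM at 0 dpi and 9.86 ± 0.697 at 3 dpi. Of 29 lysosome genes tested, 23 were higher, 2 were lower and 4 did not pass the test (23 higher and 2 lower adjusted over the list alone). Lysosome genes had a median log2 fold change of 0.65 (camera adjusted p = 2.82e-06, adjusted p = 0.370 with an estimated correlation). Of 21 phagocytosis genes tested, 16 were higher, 4 were lower and 1 did not pass the test (16 higher and 4 lower adjusted over the list alone). Phagocytosis genes had a median log2 fold change of 1.43 (camera adjusted p = 0.000166, adjusted p = 0.290 with an estimated correlation). Cd5l, a secreted scavenger receptor-like protein, rose by 4.05, while Clec4n, Timd4 and Cd93 had 29.4%, 56.6% and 43.5% of their counts within reach of free RNA.

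Of 23 cytokine and chemokine genes tested, 15 were higher, 2 were lower and 6 did not pass the test (15 higher and 2 lower adjusted over the list alone). Cytokine and chemokine genes had a median log2 fold change of 0.82 (camera adjusted p = 0.00101, adjusted p = 0.370 with an estimated correlation). Il1b, an inflammatory cytokine, rose from 15.3 to 192 ± 11.4 CPM (3.65), and Il1rn, the antagonist of its receptor, rose by 4.53. Of 17 complement genes tested, 14 were higher, 2 were lower and 1 did not pass the test (14 higher and 2 lower adjusted over the list alone). Complement genes had a median log2 fold change of 0.59 (camera adjusted p = 7.17e-05, adjusted p = 0.290 with an estimated correlation). C4b rose from 1.07 to 25.5 ± 0.0362 CPM (4.57). Of 25 interferon response genes tested, 14 were higher, 0 were lower and 11 did not pass the test (14 higher and 0 lower adjusted over the list alone). Interferon response genes had a median log2 fold change of 0.47 (camera adjusted p = 0.00167, adjusted p = 0.483 with an estimated correlation). Of 19 antigen presentation genes tested, 12 were higher, 2 were lower and 5 did not pass the test (12 higher and 2 lower adjusted over the list alone). Antigen presentation genes had a median log2 fold change of 0.33 (camera adjusted p = 0.00626, adjusted p = 0.337 with an estimated correlation). Nlrc5, an activator of class I genes, rose by 2.36, while H2-Aa and H2-Eb1 had 68.0% and 74.9% of their counts within reach of free RNA. Of 18 growth factor and alternative activation genes tested, 9 were higher, 3 were lower and 6 did not pass the test (9 higher and 3 lower adjusted over the list alone). Growth factor and alternative activation genes had a median log2 fold change of 0.74 (camera adjusted p = 0.0122, adjusted p = 0.370 with an estimated correlation). With free RNA subtracted, that list no longer passed the preset-correlation test (median 0.63).

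Genes of DNA replication fell relative to all counts. Of 42 S-phase genes tested, 0 were higher, 41 were lower and 1 did not pass the test (0 higher and 41 lower adjusted over the list alone). S-phase genes had a median log2 fold change of -1.08 (camera adjusted p = 1.70e-12, adjusted p = 0.337 with an estimated correlation). Hells, a helicase of replicating cells, fell from 29.7 to 8.71 ± 0.961 CPM (-1.76). Of 51 G2/M genes tested, 4 were higher, 32 were lower and 15 did not pass the test (4 higher and 32 lower adjusted over the list alone). G2/M genes had a median log2 fold change of -0.40 (camera adjusted p = 0.00101, adjusted p = 0.622 with an estimated correlation). Lbr, a receptor of the inner nuclear membrane, fell (-1.28) and Psrc1, a spindle protein, rose (1.01). The G2/M list, of which Mki67 is a member, lost its call with cycling cells left out (median -0.18). Those cells were chosen by at least 3 UMIs over the S-phase or G2/M list. Leaving them out therefore selects on the tested genes and does not test their fall. Mki67, a marker of proliferating cells, fell by 0.46 on the log2 scale (edgeR adjusted p = 0.0190) but stood at 0.52 with cycling cells left out.

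Of 37 oxidative phosphorylation genes tested, 35 were higher, 0 were lower and 2 did not pass the test (36 higher and 0 lower adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of 0.67 (camera adjusted p = 4.66e-11, adjusted p = 0.290 with an estimated correlation). Cox5b, a subunit of cytochrome c oxidase, rose from 175 to 347 ± 1.80 CPM (0.99). Of 20 glycolysis genes tested, 12 were higher, 4 were lower and 4 did not pass the test (12 higher and 4 lower adjusted over the list alone). Glycolysis genes had a median log2 fold change of 0.63 (camera adjusted p = 0.0180, adjusted p = 0.483 with an estimated correlation). Of 22 cholesterol synthesis genes tested, 3 were higher, 15 were lower and 4 did not pass the test (3 higher and 15 lower adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change of -0.50 (camera adjusted p = 0.00168, adjusted p = 0.321 with an estimated correlation). In all called cells, with no class chosen, the cholesterol list no longer passed (median -0.19), nor did glycolysis with cycling cells left out (0.51). Of 21 hypoxia, iron and oxidative stress genes tested, 14 were higher, 1 was lower and 6 did not pass the test (15 higher and 1 lower adjusted over the list alone). Hypoxia, iron and oxidative stress genes had a median log2 fold change of 1.07 (camera adjusted p = 2.19e-05, adjusted p = 0.337 with an estimated correlation).

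Markers of other cell types moved in the same sums. Of 9 border-associated macrophage markers tested, 8 were higher, 0 were lower and 1 did not pass the test (9 higher and 0 lower adjusted over the list alone). Border-associated macrophage markers had a median log2 fold change of 2.57 (camera adjusted p = 5.42e-05, adjusted p = 0.337 with an estimated correlation). Lyve1, Cd163, F13a1 and Ms4a7 had 92.9%, 89.1%, 61.1% and 25.6% of their counts within reach of free RNA. Of 10 monocyte markers tested, 9 were higher, 0 were lower and 1 did not pass the test (9 higher and 0 lower adjusted over the list alone). Monocyte markers had a median log2 fold change of 2.68 (camera adjusted p = 4.82e-06, adjusted p = 0.299 with an estimated correlation). Of 10 neutrophil markers tested, 7 were higher, 1 was lower and 2 did not pass the test (8 higher and 1 lower adjusted over the list alone). Neutrophil markers had a median log2 fold change of 2.43 (camera adjusted p = 0.00888, adjusted p = 0.462 with an estimated correlation). Over all 36 lists, camera called 24 with the preset correlation (19 higher, 5 lower). With an estimated correlation it called 0 after adjustment and 6 at an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 30.

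**Figure D2:**
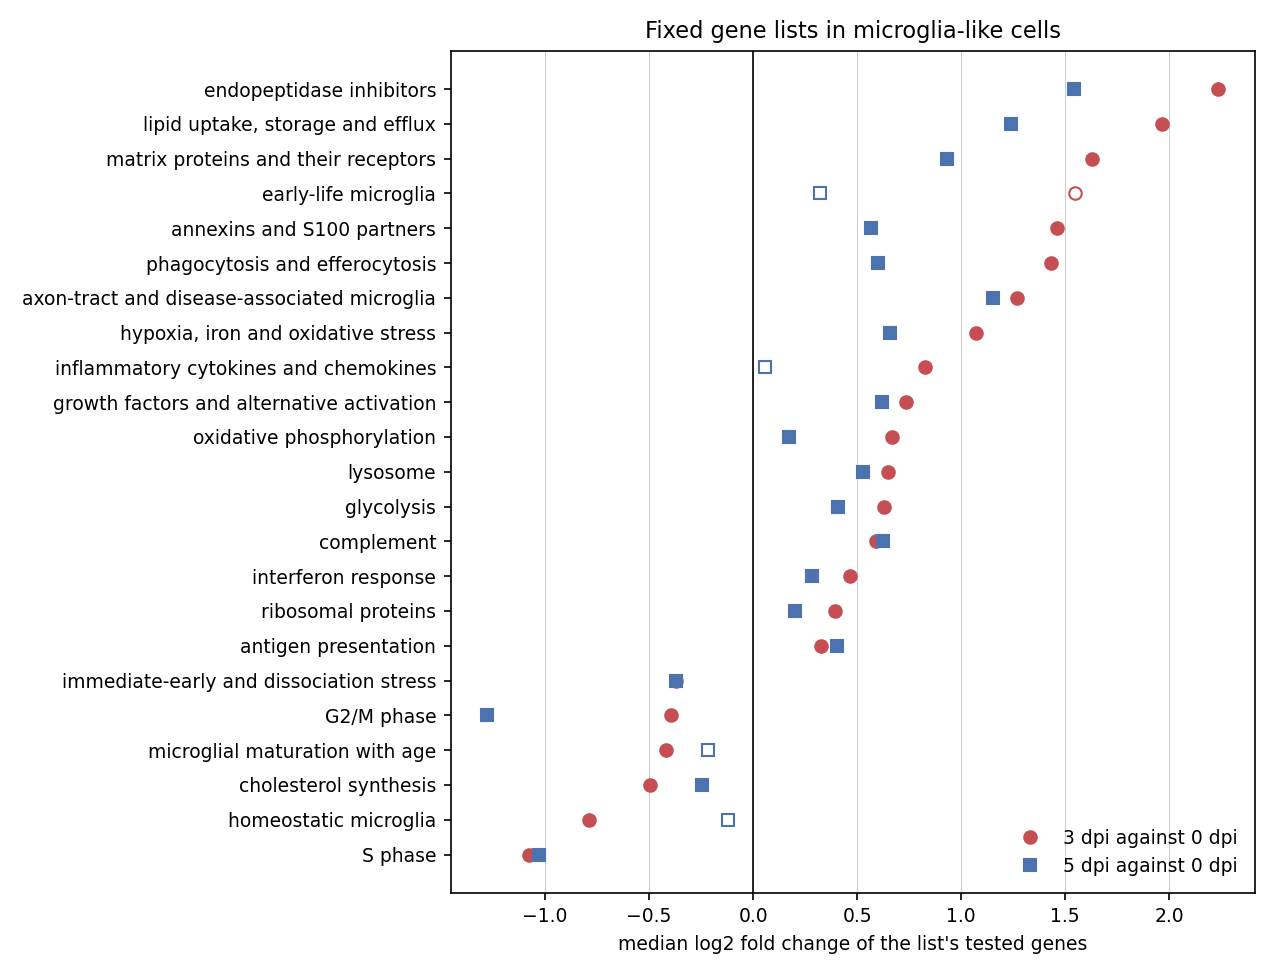
Median log2 fold change against 0 dpi (horizontal axis) of 23 gene lists in microglia-like sums, with circles for 3 dpi and squares for 5 dpi, S-phase genes at -1.08 and -1.03 and lipid genes at 1.97 and 1.24. Filled symbols passed camera with the preset correlation and open ones did not, and the open circle of the stress list lies hidden under its square at -0.37.

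The second comparison asked what differed 5 days after the crush. Fn1 (129 ± 10.3 CPM, SD, n = 2, log2 fold change 6.25, SE 0.109, edgeR adjusted p = 1.09e-13) and Spp1 (547 ± 5.50 CPM, log2 fold change 3.55, SE 0.101, edgeR adjusted p = 4.76e-10) were again the genes with the highest fold changes under the naming rule. Wfdc17 (3.53), Pla2g7 (3.42), Gpnmb (3.00), Cd72 (2.90), Apoc1 (2.85) and Chst1, a carbohydrate sulfotransferase (2.45), were higher too. Klf2, a transcription factor, fell from 1573 to 434 ± 0.323 CPM (log2 fold change -1.86, SE 0.0609, edgeR adjusted p = 6.14e-11). Genes of dividing cells fell, such as the topoisomerase Top2a (-1.43), the ubiquitin-conjugating enzyme Ube2c (-1.55), the microtubule regulator Stmn1 (-1.47) and Cdca8 (-1.49), and so did Igfbp4, which binds insulin-like growth factors (-1.52), and the glucocorticoid-induced Tsc22d3 (-1.41).

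A total of 5631 of 14253 genes passed edgeR's test, 2761 higher and 2870 lower, and 1054 were at least 2-fold apart. The count was 3576 without 5 dpi replicate 1, 3524 without replicate 2, 3274 with DESeq2, 3728 with cycling cells left out and 1052 with a mitochondrial limit of 5%. Under that limit Fn1 (6.19) and Spp1 (3.16) did not pass, and Gpnmb did not at the 0.3 marker level (1.41). Of the genes named here, Ube2c lost its call without either 3 dpi library, Gpnmb at a threshold of 3000 UMIs (3.41), and Cdca8 with cycling cells left out (-0.80). The cycling cells were chosen by lists that hold Cdca8.

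Of 23 axon-tract and disease-associated genes tested, 21 were higher, 0 were lower and 2 did not pass the test (22 higher and 0 lower adjusted over the list alone). Axon-tract and disease-associated genes had a median log2 fold change of 1.15 (camera adjusted p = 4.70e-13, adjusted p = 0.352 with an estimated correlation). Cst7, an inhibitor of lysosomal cysteine proteases, rose from 5.55 to 44.6 ± 2.49 CPM (3.01), Itgax, the integrin subunit CD11c, from 2.43 to 16.3 ± 0.512 CPM (2.75), Igf1 to 71.3 ± 1.33 CPM (1.98) and Apoe to 28503 ± 352 CPM (1.75). Of 22 homeostatic genes tested, 3 were higher, 9 were lower and 10 did not pass the test (3 higher and 10 lower adjusted over the list alone). Homeostatic genes had a median log2 fold change of -0.12 (camera adjusted p = 0.0854, adjusted p = 0.352 with an estimated correlation). P2ry12 was at 1427 ± 26.8 CPM (-0.41) and Tmem119 at 545 ± 9.64 CPM (-0.28, a call lost without 5 dpi replicate 1). Of 26 genes of matrix proteins and their receptors tested, 18 were higher, 1 was lower and 7 did not pass the test (20 higher and 1 lower adjusted over the list alone). Matrix and matrix receptor genes had a median log2 fold change of 0.93 (camera adjusted p = 4.75e-07, adjusted p = 0.304 with an estimated correlation). Mmp12, a metalloproteinase of macrophages, rose (3.17, a call lost with cycling cells left out), and Thbs1 was at 0.50, a call lost when free RNA was subtracted (0.04). Of 24 endopeptidase inhibitor genes tested, 16 were higher, 1 was lower and 7 did not pass the test (16 higher and 1 lower adjusted over the list alone). Endopeptidase inhibitor genes had a median log2 fold change of 1.54 (camera adjusted p = 1.97e-06, adjusted p = 0.304 with an estimated correlation). With 2 members that had no count at 0 dpi set at their bound of 3 counts, that median was 1.42. Of 13 annexin and S100 genes tested, 9 were higher, 2 were lower and 2 did not pass the test (9 higher and 2 lower adjusted over the list alone). Annexin and S100 genes had a median log2 fold change of 0.57 (camera adjusted p = 0.00231, adjusted p = 0.352 with an estimated correlation). With free RNA subtracted the annexin list no longer passed, and Anxa1 (2.61) did not either. These lists, as at 3 dpi, include themes of the study itself.

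Of 20 genes of lipid uptake, storage and efflux tested, 17 were higher, 0 were lower and 3 did not pass the test (17 higher and 0 lower adjusted over the list alone). Lipid uptake, storage and efflux genes had a median log2 fold change of 1.24 (camera adjusted p = 1.41e-08, adjusted p = 0.304 with an estimated correlation). Olr1, a receptor for oxidised lipoprotein, rose (3.42), and Cd36 was higher by 1.82 but at -0.14 with a mitochondrial limit of 5%. Of 29 lysosome genes tested, 23 were higher, 0 were lower and 6 did not pass the test (25 higher and 0 lower adjusted over the list alone). Lysosome genes had a median log2 fold change of 0.53 (camera adjusted p = 2.23e-09, adjusted p = 0.338 with an estimated correlation). The proteases Ctsd (1.12) and Ctsb (0.88) rose. Of 17 complement genes tested, 14 were higher, 0 were lower and 3 did not pass the test (15 higher and 0 lower adjusted over the list alone). Complement genes had a median log2 fold change of 0.62 (camera adjusted p = 3.13e-07, adjusted p = 0.304 with an estimated correlation). C4b reached 26.9 ± 1.25 CPM (4.64). Of 19 antigen presentation genes tested, 16 were higher, 1 was lower and 2 did not pass the test (16 higher and 1 lower adjusted over the list alone). Antigen presentation genes had a median log2 fold change of 0.40 (camera adjusted p = 2.87e-06, adjusted p = 0.304 with an estimated correlation). Of 21 phagocytosis genes tested, 13 were higher, 2 were lower and 6 did not pass the test (15 higher and 2 lower adjusted over the list alone). Phagocytosis genes had a median log2 fold change of 0.60 (camera adjusted p = 6.52e-05, adjusted p = 0.304 with an estimated correlation). Of 23 cytokine and chemokine genes tested, 8 were higher, 4 were lower and 11 did not pass the test (8 higher and 4 lower adjusted over the list alone). Cytokine and chemokine genes had a median log2 fold change of 0.06 (camera adjusted p = 0.276, adjusted p = 0.670 with an estimated correlation). Lgals3 did not pass in edgeR (log2 2.04, adjusted p = 0.0896), while DESeq2 called it (2.05).

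Of 42 S-phase genes tested, 0 were higher, 40 were lower and 2 did not pass the test (0 higher and 40 lower adjusted over the list alone). S-phase genes had a median log2 fold change of -1.03 (camera adjusted p = 6.71e-18, adjusted p = 0.304 with an estimated correlation). Of 51 G2/M genes tested, 0 were higher, 51 were lower and 0 did not pass the test (0 higher and 51 lower adjusted over the list alone). G2/M genes had a median log2 fold change of -1.28 (camera adjusted p = 3.34e-20, adjusted p = 0.352 with an estimated correlation). Mki67 fell from 139 to 61.3 ± 0.163 CPM (-1.19). Of 37 oxidative phosphorylation genes tested, 16 were higher, 0 were lower and 21 did not pass the test (17 higher and 0 lower adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of 0.17 (camera adjusted p = 0.000404, adjusted p = 0.304 with an estimated correlation). Of 22 cholesterol synthesis genes tested, 0 were higher, 10 were lower and 12 did not pass the test (0 higher and 13 lower adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change of -0.25 (camera adjusted p = 0.00243, adjusted p = 0.304 with an estimated correlation). In all called cells the cholesterol list did not pass (median -0.07). Glycolysis (0.41), hypoxia and iron (0.66), growth factor (0.62) and interferon (0.29) medians were above 0 with camera adjusted p of 0.00164, 1.82e-05, 0.00150 and 0.0146. Their adjusted p = 0.393, 0.338, 0.338 and 0.552 with an estimated correlation, and the interferon list did not pass without 5 dpi replicate 2 (median 0.17).

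Monocyte (1.36), neutrophil (2.74), border macrophage (1.13) and astrocyte (1.02) markers had medians above 0 in the same sums, with 8 of 10, 6 of 10, 4 of 9 and 6 of 7 genes higher (1 neutrophil marker was lower). Their camera adjusted p were 1.04e-05, 0.000781, 0.00164 and 0.000781, and adjusted p = 0.304, 0.352, 0.352 and 0.304 with an estimated correlation. With free RNA subtracted, border macrophage (0.13) and astrocyte (0.60) markers lost their calls, monocyte markers kept theirs and neutrophil markers gave no value. Astrocyte markers also lost theirs in all called cells. Camera called 23 of 36 lists (19 higher, 4 lower), 0 with an estimated correlation after adjustment and 4 at an unadjusted p under 0.05, and fry called 28.

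The third comparison set 5 dpi against 3 dpi. Spp1 fell from 3635 ± 409 to 547 ± 5.50 CPM (SD, n = 2, log2 fold change -2.73, SE 0.0719, edgeR adjusted p = 1.31e-10) and Fn1 from 548 ± 17.6 to 129 ± 10.3 CPM (log2 fold change -2.09, SE 0.0573, edgeR adjusted p = 8.43e-12). Gpnmb (-2.19), Pla2g7 (-2.17), Wfdc17 (-2.08) and Cxcl2, a chemokine for neutrophils (-2.15), fell as well. Crybb1 rose from 159 ± 6.54 to 552 ± 0.641 CPM (log2 fold change 1.79, SE 0.0499, edgeR adjusted p = 8.43e-12), as did Fscn1 (1.51), the adhesion receptor Adgrg1 (1.46), the inhibitory receptor Lag3 (1.44), the selectin ligand Selplg (1.34) and the cytokine co-receptor Il6st (1.25). Igf1 (-0.87), Cd36 (-1.62) and Mki67 (-0.73) were lower at 5 dpi, with Mki67 at 0.64 under a mitochondrial limit of 5%. Apoe had a log2 fold change of -0.21, a call lost without either 5 dpi library and turned in all called cells (0.00686).

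Between these groups 7478 of 14253 genes passed edgeR's test, 3597 higher and 3881 lower at 5 dpi, with 1092 at least 2-fold apart. With a mitochondrial limit of 5% the count was 2396, and Spp1 (-2.82), Fn1 (-2.67) and Gpnmb (-0.52) did not pass. At the 0.3 marker level Gpnmb did not pass (-2.24). Lgals3 (-1.59, adjusted p = 0.0624) did not pass in edgeR but did in DESeq2 (-1.61), and Thbs1 (-1.21) and Anxa1 (-1.11) passed, although Anxa1 did not with free RNA subtracted and stood at 0.0816 in all called cells.

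Of 22 homeostatic genes tested, 20 were higher, 0 were lower and 2 did not pass the test (20 higher and 0 lower adjusted over the list alone). Homeostatic genes had a median log2 fold change of 0.66 (camera adjusted p = 1.06e-08, adjusted p = 0.488 with an estimated correlation). P2ry12 (1.18) and Tmem119 (1.23) were among those that rose. Of 51 G2/M genes tested, 0 were higher, 42 were lower and 9 did not pass the test (0 higher and 43 lower adjusted over the list alone). G2/M genes had a median log2 fold change of -0.88 (camera adjusted p = 1.63e-10, adjusted p = 0.637 with an estimated correlation). This list was not tested under a mitochondrial limit of 5%, where Mki67 turned. The mitotic cyclin Ccnb2 fell from 52.1 ± 4.58 to 13.8 ± 1.20 CPM (-1.92). Of 42 S-phase genes tested, 19 were higher, 7 were lower and 16 did not pass the test (19 higher and 7 lower adjusted over the list alone). S-phase genes had a median log2 fold change of 0.21 (camera adjusted p = 0.103, adjusted p = 0.762 with an estimated correlation). Of 37 oxidative phosphorylation genes tested, 0 were higher, 35 were lower and 2 did not pass the test (0 higher and 35 lower adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of -0.50 (camera adjusted p = 9.01e-11, adjusted p = 0.488 with an estimated correlation). Of 20 genes of lipid uptake, storage and efflux tested, 0 were higher, 16 were lower and 4 did not pass the test (0 higher and 17 lower adjusted over the list alone). Lipid uptake, storage and efflux genes had a median log2 fold change of -0.55 (camera adjusted p = 5.89e-05, adjusted p = 0.488 with an estimated correlation). Of 23 cytokine and chemokine genes tested, 1 was higher, 15 were lower and 7 did not pass the test (1 higher and 16 lower adjusted over the list alone). Cytokine and chemokine genes had a median log2 fold change of -0.47 (camera adjusted p = 0.000382, adjusted p = 0.488 with an estimated correlation). Il1b fell to 59.1 ± 6.60 CPM (-1.70). Of 13 annexin and S100 genes tested, 1 was higher, 12 were lower and 0 did not pass the test (1 higher and 12 lower adjusted over the list alone). Annexin and S100 genes had a median log2 fold change of -0.99 (camera adjusted p = 3.50e-05, adjusted p = 0.488 with an estimated correlation). Of 26 genes of matrix proteins and their receptors tested, 5 were higher, 15 were lower and 6 did not pass the test (5 higher and 15 lower adjusted over the list alone). Matrix and matrix receptor genes had a median log2 fold change of -0.42 (camera adjusted p = 0.0102, adjusted p = 0.488 with an estimated correlation).

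Of 23 axon-tract and disease-associated genes tested, 6 were higher, 10 were lower and 7 did not pass the test (6 higher and 11 lower adjusted over the list alone). This list was not called by camera in limma (adjusted p = 0.328), and its median of 0.01 and mean of -0.33 differed in sign. Cst7 (1.26) and Itgax (1.16) rose (Itgax not with a mitochondrial limit of 5%, 0.07) while Spp1, Gpnmb and Fabp5 (-1.57) fell, the last a call lost without either 5 dpi library. Phagocytosis genes had a median of -0.45 and hypoxia and iron genes of -0.47, with camera adjusted p of 0.0144 and 0.0455 and adjusted p = 0.488 and 0.637 with an estimated correlation. The hypoxia and iron call was lost with DESeq2 size factors and the phagocytosis call in all called cells. Growth factor and complement lists, which limma's camera did not call (adjusted p = 0.640 and 0.617), had medians above 0 (0.20 and 0.07) and means at or below it (-0.0023 and -0.06).

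Border macrophage (-1.28) and monocyte (-1.25) markers had medians below 0 in these sums, with 7 of 9 and 8 of 10 genes lower and 0 higher. Astrocyte (0.73) and oligodendrocyte lineage (0.63) markers had medians above 0, with 7 of 7 and 3 of 8 higher and 0 lower. Their camera adjusted p were 0.000394, 5.89e-05, 0.000488 and 0.0167, each with adjusted p = 0.488 with an estimated correlation. Oligodendrocyte lineage markers lost their call with free RNA subtracted (0.40), and astrocyte markers in all called cells (-0.13). Camera called 15 of 36 lists (4 higher, 11 lower), 0 with an estimated correlation after adjustment and 2 at an unadjusted p under 0.05, and fry called 19.

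Whether genes moved back toward the intact level was measured by choosing genes in one 3 dpi library and measuring them from the other. Over both ways round there were 502 choices of genes with a mean of at least 32 CPM over all libraries and at least 2-fold from 0 dpi in the 1 library, of 285 distinct genes with 217 chosen in both libraries. Of the choices, 95.4% had moved in the direction of 0 dpi by 5 dpi. Genes chosen as far from 0 dpi at 3 dpi would mostly lie nearer at any other level, so this share is a description and not a test of return. Per library and direction the share was 97.9% of 189 and 93.9% of 179 genes chosen as higher, and 97.0% of 66 and 91.2% of 68 chosen as lower.

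**Figure D3:**
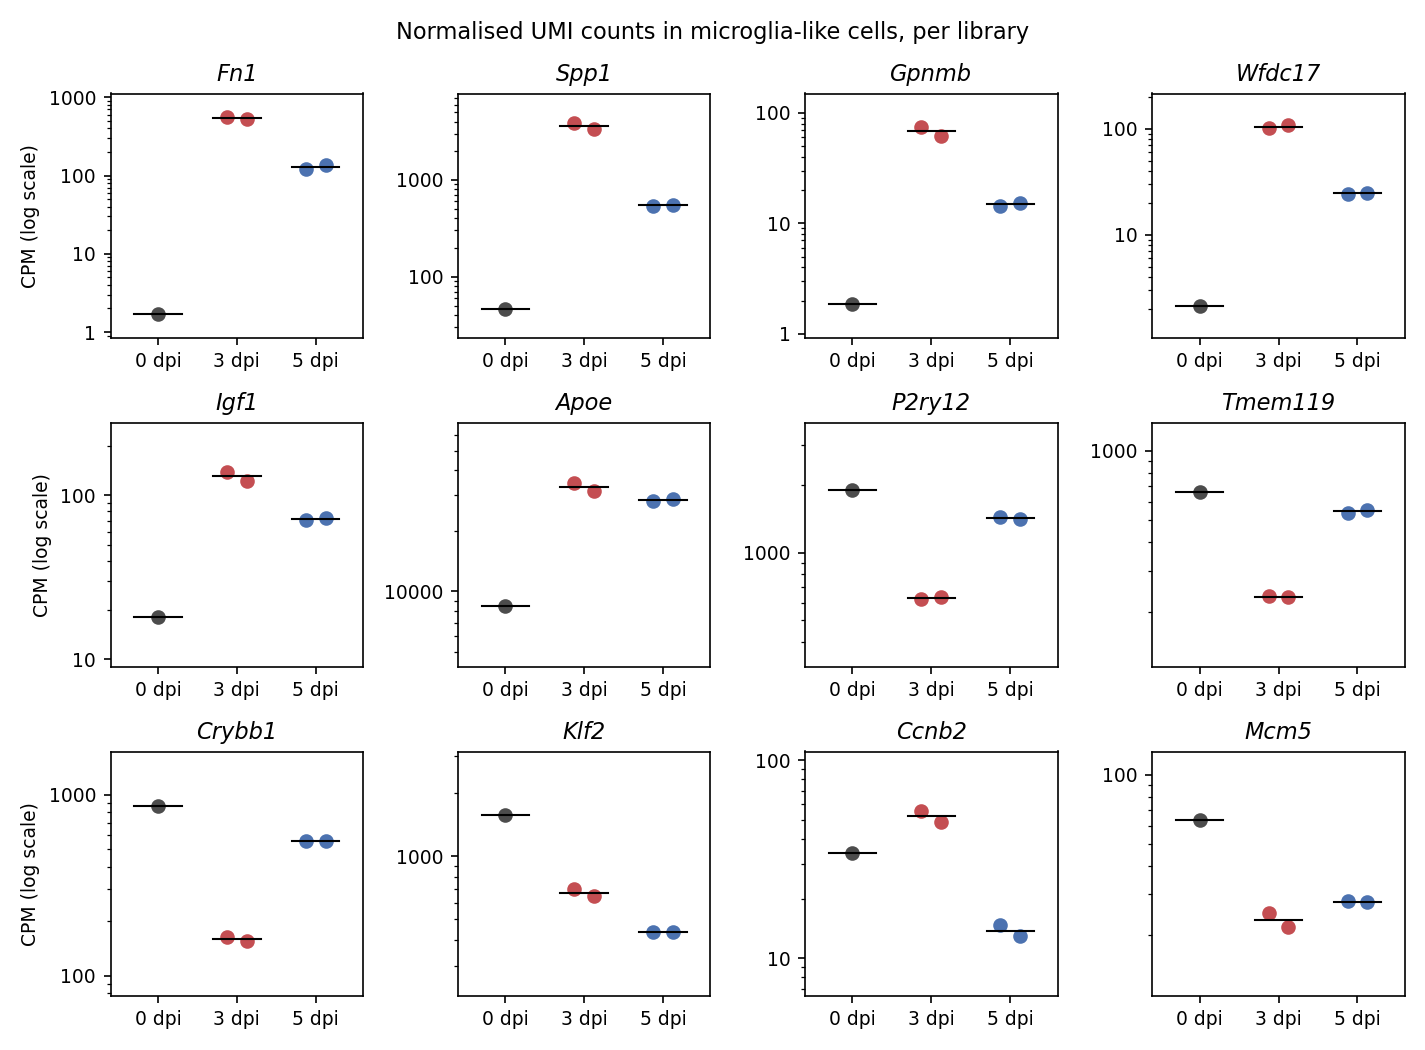
CPM (log axis) of 12 genes in microglia-like sums at 0, 3 and 5 dpi, with points for libraries and lines for group means. Fn1 and Spp1 peak at 3 dpi, P2ry12, Tmem119 and Crybb1 are lowest there, and Klf2 is lowest at 5 dpi.

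The share of microglia-like cells with a UMI was counted after thinning each cell to 2000 UMIs, which left out 0 cells. Spp1 was found in 4.19% of cells at 0 dpi, 62.8% ± 0.257 at 3 dpi and 18.8% ± 0.221 at 5 dpi (SD, n = 2), against 5.88% of 102 oligodendrocyte lineage-like cells. Fn1 was found in 0.217%, 41.7% ± 0.166 and 10.4% ± 1.21, against 0.980% of those cells. Of these 102 cells, 8 came from the 0 dpi library, so they do not give the background at 0 dpi. Igf1 was found in 3.71%, 17.0% ± 0.704 and 10.2% ± 1.23, against 0 of 102. P2ry12 was found in 96.1%, 65.2% ± 0.782 and 89.0% ± 0.0260, against 10.8%, and Tmem119 in 71.6%, 34.5% ± 0.782 and 63.8% ± 0.658, against 0.980%. Mki67 was found in 12.5%, 9.03% ± 0.105 and 5.16% ± 1.05, against 9.80% of the oligodendrocyte lineage-like cells, which can divide themselves. Without thinning, Spp1 was in 12.7%, 94.6% and 49.8%, Fn1 in 0.935%, 82.2% and 33.1%, Igf1 in 15.3%, 63.9% and 43.8%, P2ry12 in 99.9%, 99.6% and 99.9%, Tmem119 in 98.3%, 92.1% and 98.1% and Mki67 in 22.8%, 24.7% and 11.2%, so the Mki67 share was lower at 3 dpi than at 0 dpi only after thinning. Median UMIs were 10093, 20252.5 and 16643.5 in microglia-like cells (means of library medians in the injured groups) and 24696 in the oligodendrocyte lineage-like cells.

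Cells with at least 3 thinned UMIs over the G2/M list made up 48.8% of microglia-like cells at 0 dpi, 33.9% ± 0.127 at 3 dpi and 26.2% ± 2.26 at 5 dpi (SD, n = 2). Over the S-phase list the shares were 42.5%, 14.4% ± 0.0520 and 23.1% ± 0.492, and over either list 63.4%, 39.0% ± 0.487 and 38.9% ± 0.756. Summed levels followed the same order, at 3258, 2264 and 1507 CPM for G2/M and 1759, 769.5 and 924 CPM for S phase. Under a mitochondrial limit of 5%, which left few injured cells, the share over either list was higher at 5 dpi than at 3 dpi, as given below. Unthinned shares over either list were 99.8%, 100% and 99.97%, so they cannot separate the groups. These are shares past a UMI threshold, and free RNA and non-cycling expression of list members can add to them. Clusters led by mitotic genes did not all shrink at 3 dpi. Cluster 12 (Ccnb2, Birc5 and Cdc20) held 0.284% of microglia-like cells at 0 dpi and 10.4% and 9.70% at 3 dpi. Cluster 15 (Hist1h2ap, Top2a and Mki67) held 0.0334%, then 8.61% and 6.76%. Clusters 10 (led by Top2a) and 20 (Cenpf) fell from 8.87% and 3.91% to at most 0.699% and 0.0489%. The shares past the threshold therefore do not settle whether fewer cells divided at 3 dpi.

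Border-associated macrophage-like cells were the other class with enough cells in every library. At 3 dpi their Fn1 rose by log2 6.56 (SE 0.548, edgeR adjusted p = 0.0131) and Spp1 by 4.86 (SE 0.502, adjusted p = 0.0491). Lgals3 (3.77) rose, and the immediate-early factor Egr1 (-1.61) fell. Part of this can be RNA of microglia, whose markers in these sums stood at a median of 10.6% of their microglia-like level at 0 dpi and 14.0% and 12.3% at 3 dpi. RNA at that share would give 41.5% and 30.1% of Spp1 at 3 dpi and 9.03% and 7.04% of Fn1, and without it their log2 differences from 0 dpi were 4.31 and 6.26 (CPM plus 1, not tested). It would give 85.3% and 76.8% of Apoc1, and 90.0% of Crybb1 in both, so these are not read as changes of this class. At 5 dpi, in edgeR, Fn1 (3.77, adjusted p = 0.128) and Spp1 (3.01, adjusted p = 0.171) did not pass. From 3 to 5 dpi Fn1 (-2.79), Lgals3 (-2.09) and the actin-capping Capg (-1.86) fell. Counts of genes include any moved by such RNA. Of 10171 genes tested, 845 passed at 3 dpi against 0 dpi (506 higher, 339 lower), 403 at 5 dpi against 0 dpi (227 and 176) and 1849 between 5 and 3 dpi (871 and 978). The 0 dpi sum rested on 70 cells and 746936 UMIs. DESeq2 called 303, 118 and 405 genes. Without 5 dpi replicate 1 the last 2 edgeR counts were 221 and 1119, and without replicate 2 they were 216 and 847.

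On build GRCm38, Fn1 lies on chromosome 1, 71585520 to 71653200, minus strand, Spp1 on chromosome 5, 104435118 to 104441050, plus strand, Gpnmb on chromosome 6, 49036546 to 49070929, plus strand, and Igf1 on chromosome 10, 87858265 to 87937042, plus strand. Crybb1 lies on chromosome 5, 112255815 to 112269585, plus strand, P2ry12 on chromosome 3, 59216272 to 59262871, minus strand, Tmem119 on chromosome 5, 113793729 to 113800516, minus strand, Klf2 on chromosome 8, 72319033 to 72321656, plus strand and Ccnb2 on chromosome 9, 70407692 to 70421547, minus strand. All are annotated as protein-coding genes, and 3' counts do not separate their exons or isoforms. Their identifiers in the files are ENSMUSG00000026193, ENSMUSG00000029304, ENSMUSG00000029816, ENSMUSG00000020053, ENSMUSG00000029343, ENSMUSG00000036353, ENSMUSG00000054675, ENSMUSG00000055148 and ENSMUSG00000032218.

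As a check of sex make-up, Xist, transcribed from the inactive X chromosome, was at 416 CPM at 0 dpi, 451 ± 3.80 at 3 dpi and 875 ± 31.3 at 5 dpi, and the Y-linked Ddx3y at 69.0, 60.7 ± 1.40 and 46.9 ± 0.227 CPM (SD, n = 2). Both were present in every library, and both differed between 5 and 3 dpi (log2 0.96 and -0.37). The Y-linked Eif2s3y, Kdm5d and Uty were at 65.5, 12.6 and 13.8 CPM at 0 dpi. They were at 62.3 ± 2.45, 10.5 ± 0.611 and 12.2 ± 0.962 CPM at 3 dpi, and at 39.4 ± 2.46, 7.73 ± 0.387 and 8.36 ± 0.374 CPM at 5 dpi. Sex make-up may therefore differ at 5 dpi, and the comparisons with 5 dpi do not separate it from time after injury.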

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

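Of the tests in this part, those of random doublets, of 1 cell of each class per barcode, of free RNA and of depth were chosen only after the result was seen.

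Many barcodes of the injured libraries lay in clusters with markers or leading genes of another class. Random doublets at loading predict 4.41% to 5.37% there, but 25.2% to 32.3% were held out, at least 5.63 times as many. That argues against doublets as the whole cause, while at 0 dpi the ratio was 0.571. Clusters held out for markers of a second class alone had 16.1% to 25.0% of injured cells, also above the prediction. In the cluster led by Retnlg, the median of 42145.5 UMIs was 1.38 times that of random pairs of 1 microglia-like and 1 large neutrophil-like barcode, but 20.9% of pairs reached that median, so exactly 1 cell of each stays open. Aggregates of several cells and RNA taken up by phagocytes may contribute and stay open, as does age, which was not tested.

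Spp1 and Fn1 were higher in microglia-like sums at 3 dpi. Free RNA gave at most 4.47% of their counts there at the share used, and 9.48% at the median of the lists, so it does not account for the rise. Monocyte-like or border macrophage-like cells mixed in gave at most 1.77% of the rise. That value was estimated from the markers that also named the classes, so it was bound to be low. It would also miss cells without these markers, so this source stays open. Cells of the unnamed clusters were not tested as a source. A response of microglia to the crush is a candidate explanation, as is postnatal age, and these were not separated by the design.

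S-phase genes were lower at 3 and 5 dpi than at 0 dpi. With all called cells summed their median was -1.21 at 3 dpi and -1.11 at 5 dpi. That sum also takes in cells of other classes, which were more frequent in the injured libraries. It therefore cannot tell cycling cells held out of the class from a change in the mix of cells. After thinning, the 0 dpi share was 1.81 times the highest injured share, which argues against unequal depth of the counted cells. Thinned counts and CPM are relative, so they cannot tell fewer S-phase transcripts per cell from more of other RNA. Median UMIs per microglia-like cell were 10093 at 0 dpi, 20252.5 at 3 dpi and 16643.5 at 5 dpi (means of library medians in the injured groups). Less replication after injury and less with age may both give lower S-phase levels, and age was not tested.

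Named genes called against 0 dpi in opposite directions at 3 and 5 dpi, which the test between 5 and 3 dpi also called, had log2 fold changes between 5 and 3 dpi of -0.75 (Atf3), -1.92 (Ccnb2), -1.68 (Cdca3), -0.98 (Cebpb), 1.25 (Il6st), -0.78 (Klf6), 1.44 (Lag3), -1.41 (Nr4a1), -1.64 (Psrc1) and -0.69 (Rpl22l1). They are 10 of 269 such genes, 139 higher at 3 dpi and lower at 5 dpi and 130 the other way. An interaction test found 697 of 14391 genes to differ between border macrophage-like and microglia-like cells at 3 dpi against 0 dpi, and 164 at 5 dpi. That test took the border and microglia sums of a library as independent samples, and 0 dpi was 1 library, so its counts are not firm. At 3 dpi the border minus microglia difference in log2 fold change was 1.05 for P2ry12. RNA of microglia would give 87.1% of P2ry12 in border sums at 0 dpi and 49.1% and 48.7% at 3 dpi. The difference was -3.86 for Cd36, -1.63 for Apoe, -2.35 for Igf1 and -2.56 for Anxa1, a gene within reach of free RNA. Cd36 was low in microglia-like sums, at 0.907 CPM at 0 dpi and 9.86 at 3 dpi. It lost its call there with free RNA at the median of the lists. At 5 dpi the difference was -2.14 for Cd36, -0.89 for Apoe, -1.20 for Igf1 and -2.55 for Anxa1. With RNA of microglia taken out, P2ry12 in border sums at 3 dpi was log2 1.27 above 0 dpi (CPM plus 1, not tested). With that RNA its log2 fold change was -0.62, so the sign of the border change depends on it. Among the cells kept with a threshold of 1000 UMIs, a wider set than the comparisons used, neutrophil-like cells were 0.0460% at 0 dpi, 1.18% ± 0.0983 at 3 dpi and 0.961% ± 0.00914 at 5 dpi (SD, n = 2). B cell-like cells among them were 0 of 8694 at 0 dpi (3 would be 0.0345%), 1.99% ± 0.209 and 0.486% ± 0.0946.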

How the results depend on the processing

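The level of 0.3 for naming classes, free RNA at the median of the lists, and the border macrophage alternatives were chosen after seeing the data. Over all alternatives, 6291 of 6632 values of named genes kept their direction and side of the threshold, 314 lost a call, 8 gained 1 and 19 turned. Of 1286 list values, 1140 kept both, 91 lost a call, 50 gained 1 and 5 turned, and of 150 shares 71 moved by less than the spread. Lists were not tested with other UMI thresholds, mitochondrial limits, doublets kept, other resolutions, thinned sums, no filter, DESeq2's test or limma-voom. With DESeq2's size factors all 303 gene values kept direction and call, and the median over all genes lay between 0.00106 and 0.0151 on the log2 scale. These factors are medians of gene ratios, which sets that median near 0. TMM also takes most genes as unchanged, so neither scaling can show a shift of all genes. A setting that left 1 library in a group assumed that it varied like the others. The replicate numbers pair 3 and 5 dpi in 2 pairs by number only, and replicate differences were uncorrelated (r = -0.0232 across 14253 genes, which are not independent). With a replicate block, 7727 genes, 16 lists and 1896 genes in border cells differed between 5 and 3 dpi, against 7529 genes in the same 4 libraries without it.

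Counts of genes in microglia-like cells that moved by over 1.5 times, in the order 3 against 0, 5 against 0 and 5 against 3 dpi, were 2029, 1054 and 1092 with at least a 2-fold change (a stricter rule by construction) and 4129, 1052 and 2396 with a mitochondrial limit of 5%. For 5 against 0 dpi they were 3274 with DESeq2 and 3728 without cycling cells. Leaving out 1 library gave 7681 to 8628, 3524 to 7130 and 5386 to 7621 genes, and in border cells 727 to 977, 216 to 568 and 847 to 1721. DESeq2 called 303, 118 and 405 genes in border cells. With an estimated correlation 0, 0 and 0 lists passed, against 24 to 26, 23 to 24 and 15 to 18 without 1 library. The return share was 95.2% without either 5 dpi library. Except for the stricter rule, the cause was not tested.

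The microglia-like share was 89.4% at 0 dpi with 1000 UMIs and 93.0% at resolution 2. At 3 dpi it was 15.9% with a mitochondrial limit of 5% and 44.2% at level 0.3. At 5 dpi it was 63.0% with 3000 UMIs, 26.3% and 62.2% with mitochondrial limits of 5% and 20%, and 57.9% at level 0.3. The border macrophage-like share with 1000 UMIs was 0.736% at 0 dpi, 6.44% ± 0.542 at 3 dpi and 1.84% ± 0.358 at 5 dpi. The share of cells past 3 UMIs over either cell-cycle list, which is not a share of cycling cells, was at 0 dpi 60.8% with 1000 UMIs, 60.7% with 3000, 65.2% with the 5% limit and 99.8% unthinned. At 3 dpi it was 41.1% and 37.4% with 1000 and 3000 UMIs, 40.1% and 39.95% with the 5% and 20% limits, 39.8% with doublets kept, 39.95% and 40.6% at resolutions 0.5 and 2, 41.3% at level 0.3 and 100% unthinned. At 5 dpi it was 40.4% and 38.1% with 1000 and 3000 UMIs, 48.3% and 37.4% with the 5% and 20% limits, 38.0% at resolution 2 and 99.97% unthinned. The cause was not tested.

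Values that turned were as follows, and the cause was not tested. Between 5 and 3 dpi Arg1 was at 0.0185 with 3000 UMIs, 0.0224 with the 20% limit and 0.00368 at resolution 2, and Ccl8 at 0.0674 with the 20% limit and 0.0741 at resolution 2. With the 5% limit Cd36 (-0.14), Cxcl1 (-4.66), Hspa1b (0.0491) and Csf1 (-0.0834) turned for 5 against 0 dpi, and Tyms (0.19), Gmnn (0.20), Pfkp (0.62) and Mki67 (0.64) for 5 against 3 dpi. In all called cells Sqle (0.28) and Idi1 (0.0742) turned for 5 against 0 dpi, and Slc2a3 (0.42), Apoe (0.00686) and Anxa1 (0.0816) for 5 against 3 dpi. Mki67 (0.52) turned at 3 against 0 dpi without cycling cells, which were chosen by lists that hold Mki67. Platelet markers, higher in camera without passing, were called lower with fry at 3 dpi against 0 dpi (median 0.80). Medians of lists under alternatives are of log2 CPM and differ somewhat from those of edgeR's fold changes. In all called cells dendritic cell markers (3.03 at 3 dpi, 2.27 at 5 dpi) and oligodendrocyte markers at 3 dpi (0.82) turned, and the latter turned between 5 and 3 dpi with free RNA at the median of the lists (-0.15). Some calls given in the text were lost, besides those with an estimated correlation. At 3 dpi against 0 dpi these were Mki67 with 1000 UMIs (-0.20), at resolution 2 (-0.43) and at level 0.3 (-0.37), and G2/M genes with fry. At 5 dpi against 0 dpi they were interferon genes with fry and monocyte markers with free RNA at the median of the lists. Cd36 lost its call in all 3 comparisons with free RNA at the median of the lists.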

Other observations

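The lists in this part and the marrow test were fixed before the result was seen, while the rule for reading the marrow test was changed after it to take counting intervals into account. Of 24 immediate-early and dissociation stress genes tested, 9 were higher, 15 were lower and 0 did not pass the test (9 higher and 15 lower adjusted over the list alone). Stress genes at 3 dpi against 0 dpi had a median log2 fold change of -0.37 (camera adjusted p = 0.144, adjusted p = 0.610 with an estimated correlation). Of 24 stress genes at 5 dpi tested, 3 were higher, 20 were lower and 1 did not pass the test (3 higher and 20 lower adjusted over the list alone). Stress genes at 5 dpi against 0 dpi had a median log2 fold change of -0.37 (camera adjusted p = 1.40e-05, adjusted p = 0.338 with an estimated correlation). Klf2 and Jun were at -1.86 and -0.76 there. Of 13 genes of microglial maturation with age tested, 2 were higher, 10 were lower and 1 did not pass the test (2 higher and 10 lower adjusted over the list alone). Maturation genes at 3 dpi against 0 dpi had a median log2 fold change of -0.42 (camera adjusted p = 0.00381, adjusted p = 0.363 with an estimated correlation). Of 13 maturation genes between 5 and 3 dpi tested, 9 were higher, 2 were lower and 2 did not pass the test (9 higher and 2 lower adjusted over the list alone). Maturation genes at 5 dpi against 3 dpi had a median log2 fold change of 0.42 (camera adjusted p = 0.00326, adjusted p = 0.488 with an estimated correlation). At 5 dpi against 0 dpi their median was -0.22 (camera adjusted p = 0.227).

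Of 84 ribosomal protein genes at 3 dpi tested, 63 were higher, 0 were lower and 21 did not pass the test (66 higher and 0 lower adjusted over the list alone). Ribosomal protein genes at 3 dpi against 0 dpi had a median log2 fold change of 0.39 (camera adjusted p = 3.19e-10, adjusted p = 0.321 with an estimated correlation). At 5 dpi their median was 0.20 against 0 dpi and -0.15 against 3 dpi (camera adjusted p = 4.88e-07 and 5.89e-05, adjusted p = 0.338 and 0.488 with an estimated correlation). Of 11 early-life microglia genes at 3 dpi tested, 7 were higher, 3 were lower and 1 did not pass the test (8 higher and 3 lower adjusted over the list alone). Early-life genes at 3 dpi against 0 dpi had a median log2 fold change of 1.55 (camera adjusted p = 0.0642, adjusted p = 0.363 with an estimated correlation). They include Mrc1, Pf4, F13a1, Lyve1 and Ms4a7, which are also border macrophage markers. F13a1, Lyve1 and Ms4a7 had 61.1%, 92.9% and 25.6% of their counts within reach of free RNA. At 5 dpi the median of early-life genes was 0.32 against 0 dpi and -0.93 against 3 dpi (camera adjusted p = 0.275 and 0.256).

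Between 5 and 3 dpi, lists not called by camera and not yet given had medians of -0.16 (endopeptidase inhibitors, adjusted p = 0.587), -0.15 (lysosome, 0.155), -0.19 (interferon, 0.0652), 0.19 (antigen presentation, 0.391), -0.21 (glycolysis, 0.443), 0.22 (cholesterol, 0.103) and -0.07 (stress, 0.443). Marker lists that did not pass had camera adjusted p at 3 dpi against 0 dpi of dendritic cell 0.551, T or NK cell 0.296, B cell 0.188, erythroid 0.0866, platelet 0.821, neuron 0.871, endothelial 0.584, fibroblast or pericyte 0.150, astrocyte 0.542 and oligodendrocyte 0.335. At 5 dpi against 0 dpi these were dendritic cell 0.530, T or NK cell 0.991, B cell 0.978, erythroid 0.991, platelet 0.978, neuron 0.190, endothelial 0.176, fibroblast or pericyte 0.0724 and oligodendrocyte 0.227. Between 5 and 3 dpi they were dendritic cell 0.639, T or NK cell 0.443, B cell 0.155, erythroid 0.0724, platelet 0.902, neuron 0.505, endothelial 0.155, fibroblast or pericyte 0.701 and neutrophil 0.371. Median, mean and test differed in sign for dendritic cell, oligodendrocyte and neuron markers at 3 dpi, dendritic cell, T or NK, B cell and platelet markers at 5 dpi, and dendritic cell and fibroblast markers between 5 and 3 dpi.

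Genes of marrow-stage cells were looked for in the cells kept with a threshold of 1000 UMIs. The hypothesis was that marrow or bone came along with the cord alike in intact and injured animals. Barcodes with pre-B genes (Vpreb1, Vpreb3, Igll1 and Rag1) were 0.0230% at 0 dpi (2 of 8694, exact interval 0.00279 to 0.0831), 0.264 times the lowest injured share of 0.0870% (0.0283 to 0.203). The bound written beforehand was 0.333 (that is, 0.264 is below it), but the intervals overlap and the counts are few, so the pre-B genes could not decide this. Barcodes with early neutrophil genes were 0.0230% at 0 dpi (0.00279 to 0.0831) and at least 0.303% in each injured library (0.161 to 0.517 in the lowest). Those with Acp5, Ctsk and Mmp9, which macrophages can also express, were 0.0115% (0.000291 to 0.0641) and 1.20% to 3.38% (0.896 to 1.57 in the lowest). In both sets the 0 dpi interval lay below those of the injured libraries, so these shares were not alike. Among the called cells of the main comparisons, an unnamed cluster went the other way. Led by Trbc2, Trbc1 and Tcf7, and with Rag1 of the pre-B genes among its leading genes, it held 1.63% of cells at 0 dpi. In the injured libraries it held 0.0448% to 0.325%. The 0 dpi group was 1 library, and the source of these barcodes was not tested.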
